A study of Mus musculus with 3 samples.

How the data were processed

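Total RNA from the hippocampus of male mice at postnatal day 120 was compared on 3 two-colour Agilent arrays with probes of 60 bases. Per the labels, each pool held RNA of 3 animals of a group, and the older-mother pool was labelled with Cy3 and the young-mother pool with Cy5 on every array. The labels give no order of handling, and whether the pools share litters is not stated. All 3 arrays were on 1 slide and in 1 scan, so no batch term was possible.

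Per the file headers, the scanner files were made with Agilent Feature Extraction 10.10.1.1 under the 2-colour protocol, and the mean spot signals and the median local backgrounds are raw intensity values. The processed signals are intensity values too, which per the file headers were corrected for background and dye with a LOWESS curve. The log ratio column is the log10 ratio of processed Cy5 over Cy3 signals, per the file headers. Flags for spots above background, saturated, non-uniform or outlying are of another (other) kind, 0 or 1, per the file headers. The deposited value table holds log2 ratios of Cy3 over Cy5; the authors' steps are not stated in it, but normexp with offset 50 and loess applied to the median signals gave the same values, with a largest difference of 5.0e-10.

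The values were computed from the mean signals and background medians with limma 3.58.1 in R 4.3.3 (sample links read with jsonlite 2.0.0). Background was corrected by normexp with an offset of 50, and dye balance by loess with a span of 0.3 within each array, with weight 0 for control spots and for spots marked as non-uniform or outlying. Spots of a probe were averaged, which concerned 399 probes with 10 spots each. A probe was kept if it was well above background in Cy3 on all 3 arrays or in Cy5 on all 3 arrays. Of 39429 probes, 27630 were kept, 11798 were not above background and 1 had an array without a usable spot. Among the kept probes, 1448 were not above background in Cy3 on any array and 17 not in Cy5. The fold of such a probe rests on a signal near background, and Cy3 was the weaker channel on every array.

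The log2 ratio of older over young mothers was tested with an intercept in limma (lmFit and eBayes, two-sided, 2 residual degrees of freedom plus 3.42 from the prior), and p was adjusted by Benjamini-Hochberg over all kept probes. The error of a log2 ratio is given as the SD over the 3 arrays. The offset pulls the ratios of dim probes towards 0. Gene names came from the files and, for 28025 probes whose accession matched the RefSeq table (assembly GRCm38.p6), from that table, which updated 1651 symbols; 5670 probes had no gene name. The coordinates printed are those of the array files, whose build is not named, and 9.82% of them lie inside the gene of the same name in GRCm38.

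Gene lists were tested with limma's camera on 1 probe per gene, the kept probe with the highest average intensity, with a preset correlation of 0.01, for lists with at least 5 measured genes and with Benjamini-Hochberg adjustment over the 52 such lists. The 53 lists held 1077 distinct genes, of which 1009 were measured and 37 stood in over 1 list. They covered markers of hippocampal, neighbouring and blood or meningeal cell types, and gene groups of stress, activity, immunity, synapses, hormones, metabolism and chromatin. Camera compares a list with the other genes; camera with an estimated correlation and fry, which tests whether a list's genes move one way on balance, were run as alternatives.

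The lists, tests, thresholds, most alternatives and the rule for named genes were fixed before the data were examined. The rule names the 12 genes with the largest rise and the 12 with the largest fall among probes with an adjusted p under 0.05 and the same sign on all 3 arrays, leaving out clone and predicted-gene names. It also names up to 4 members with the smallest p of each shifted list, up to 2 of each other list described, and Ttr, Gfap, Bdnf, Nr3c1, Fkbp5 and Igf2 whatever their values. Where a list's few exceptions are named beyond that (Trib3, H2-Q4, Ciita, H4f16, H4c4 and Kcne2, and the added members S100a8, Camp, Per1 and Per2), they were chosen after their values were seen.

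Alternatives were Agilent's processed signals, no background correction, an offset of 16, median centring, scaling between arrays, the deposited table, no filter and a stricter filter, a variance trend with robust settings, array weights, separate channels, other thresholds, the mean over a gene's probes, and leaving out each replicate. A regression on probe base composition, and leaving out the choroid plexus and leptomeningeal genes from the list tests, were added after seeing the data.

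Background correction, loess, spot averaging and the limma fit were tested together on simulated spot signals for this comparison, with 27630 probes. Of 100 probes given a log2 change of 0.5, 43 were called, with a median estimate of 0.40, and of 100 given a change of 1, 93 were called, with a median estimate of 0.82. None of these had the wrong sign, and 9 of 145 calls were false. No dye effect of single genes was simulated, so the false calls do not cover that source. A shifted list was called by camera with the preset correlation (adjusted p = 1.1e-52) but not with an estimated one (0.222), and 0 of 49 unshifted lists were called. The simulated noise was independent between probes, so these lists had no correlation between genes. They cannot tell how often the preset correlation calls unshifted lists in the real data.

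The quality of the arrays was close: log2 ratios of probes correlated across genes at 0.602, 0.502 and 0.701 between pairs of arrays, where genes are not independent replicates, and the spread (SD) of the log2 ratios was 0.21, 0.23 and 0.23. For 302 tested probes with 10 spots the median SD between spots was 0.0529 and between arrays 0.0740. The spike-in controls gave slopes of observed on designed log ratios of 0.917, 0.920 and 0.911.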

Results

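Gene expression was measured in the hippocampus of adult male mice whose mothers were either older (15 to 18 months at breeding) or young (3 months). The fathers were 3 months old in both groups, and the offspring were killed at postnatal day 120. Each RNA sample was a pool from 3 males of 1 group, and there were 3 pools per group. Each of the 3 arrays carried 1 older-mother pool in the Cy3 dye and 1 young-mother pool in the Cy5 dye, with the same orientation on every array. Each array held 44397 spots, and the median Cy3 signal over local background was 59.2, 58.0 and 62.3 intensity units on arrays 1, 2 and 3. The median Cy5 signal over background was 154, 153 and 165 units, and 0 spots were saturated. Of the spots that are not controls, 64.6%, 66.7% and 65.6% were well above background in Cy3 and 74.8%, 74.9% and 71.0% in Cy5. The number of arrays limits the precision of all values.

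The comparison asks which hippocampal genes differ in expression between adult sons of older and of young mothers. In the older-mother pools 16 of 20 glucocorticoid-induced genes, 15 of 22 immediate early genes of neuronal activity, 11 of 15 heat shock proteins and 12 of 17 unfolded protein response genes rose, and 1 of the last list fell. Hspa1a, an inducible Hsp70 chaperone, was 3.48-fold higher, with log2 ratios of older over young of 1.92, 1.73 and 1.75 on the 3 arrays (SD 0.10, n = 3). Of choroid plexus markers 5 of 19 fell, of leptomeningeal fibroblast markers 7 of 13 and of genes of antigen presentation on MHC class I 10 of 17 (1 rose), with list medians of -0.92 (-0.46 without replicate 2), -0.38 and -0.34 on the log2 scale. These 7 lists were called by limma's camera with a preset correlation, and for each the adjusted p = 0.759 with an estimated correlation. Gbp4, an interferon-induced GTPase, was 2.69-fold lower, with a log2 ratio of -1.43 ± 0.24 (SD, n = 3).

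Of 27630 probes tested, 2189 were higher and 2946 lower in the older-mother pools (limma, Benjamini-Hochberg adjusted p under 0.05, two-sided). The smallest adjusted p was 0.00572. With the stricter filter, which asks for signal above background in both channels on all 3 arrays, 2215 were higher and 2566 lower of 24356 probes. At gene level, with the brightest probe of each of 17964 genes, 1318 genes were higher and 2183 lower. Most changes were small: the median absolute log2 ratio of the called probes was 0.27, and at least a 1.5-fold difference was seen for 119 higher and 76 lower genes. The log2 ratios had the same sign on all 3 arrays for 59.7% of probes, where chance gives 25%. Without replicate 3, 29 probes were higher and 0 lower by limma, with 8422 probes at an unadjusted p under 0.05; the counts were 356 and 376 without replicate 2 and 1459 and 1906 without replicate 1. The older-mother pool was in Cy3 on every array, so each ratio holds the dye difference as well as the group difference, and centring each array on its median in place of an intensity-dependent loess curve moved the median of all genes to -0.40 and gave 5970 higher and 17033 lower probes.

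The 12 largest rises included Lcn2, a secreted iron-binding lipocalin, with a log2 ratio of 1.69 ± 0.69 (SD, n = 3), and Hspb1, a small heat shock protein, with 1.49 ± 0.12 (SD, n = 3). Dio2, the deiodinase that makes active thyroid hormone, rose by 1.46 ± 0.18 (SD, n = 3), and Dnajb1, an Hsp40 co-chaperone, by 1.33 ± 0.21 (SD, n = 3). Gem, a small GTPase, rose by 1.32 ± 0.16, Cdkn1a, a cyclin-dependent kinase inhibitor, by 1.30 ± 0.37, the immediate early gene Egr2 by 1.29 ± 0.28 and Pdk4, an inhibitor of pyruvate dehydrogenase, by 1.23 ± 0.17 (each SD, n = 3). The other rises varied more between arrays: the defensin-related gene Defa-rs2 (2.25 ± 1.22), the chitinase-like gene Chil3 (1.74 ± 0.76) and Sdc4, the heparan sulfate proteoglycan syndecan-4 (1.65 ± 1.08, each SD, n = 3). The largest falls after Gbp4 were Kcnj13, a potassium channel of the choroid plexus, at -1.41 ± 0.99, the alpha-tubulin gene Tuba1c at -1.37 ± 0.56 and Sostdc1, a secreted BMP and Wnt antagonist, at -1.24 ± 0.78 (each SD, n = 3). They were followed by Cd74, the MHC class II invariant chain (-1.19 ± 0.59), Hes5, a target of Notch (-1.13 ± 0.16), Steap1 (-1.10 ± 0.72), Lbhd2 (-1.09 ± 0.53) and Krt18, an epithelial keratin (-1.08 ± 0.67, each SD, n = 3). H2-Ab1, an MHC class II chain (-1.01 ± 0.31), Inmt, a methyltransferase (-0.96 ± 0.48), and ND1, a mitochondrially encoded subunit of complex I (-0.91 ± 0.50, each SD, n = 3), completed the 12. Limma adjusted p ran from 0.00572 for Hspa1a to 0.0478 for Kcnj13. Without replicate 3, 7 of these 24 genes stayed past the threshold, namely Hspa1a, Hspb1, Dio2, Dnajb1, Gem, Egr2 and Pdk4, and the other 17 had limma adjusted p from 0.0515 to 0.111. Without replicate 2, Kcnj13, Sostdc1, Steap1 and Krt18 moved to -0.90, -0.79, -0.70 and -0.70. Without replicate 1 their calls ended (limma adjusted p = 0.103, 0.0655, 0.0742 and 0.0743). Without replicate 2 the calls of Sdc4 (0.0861) and ND1 (0.0537) ended.

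In the coordinates of the files, which do not name their genome build, the Hspa1a probe lies on chromosome 17 from 35107117 to 35107176 and the Hspb1 probe on chromosome 5 from 136365366 to 136365425. The Dio2 probe lies on chromosome 12 from 91963235 to 91963294, and the Gbp4 probe on chromosome 5 from 105544852 to 105544911. The Kcnj13 probe lies on chromosome 1 from 89282859 to 89282918.

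**Figure D1:**
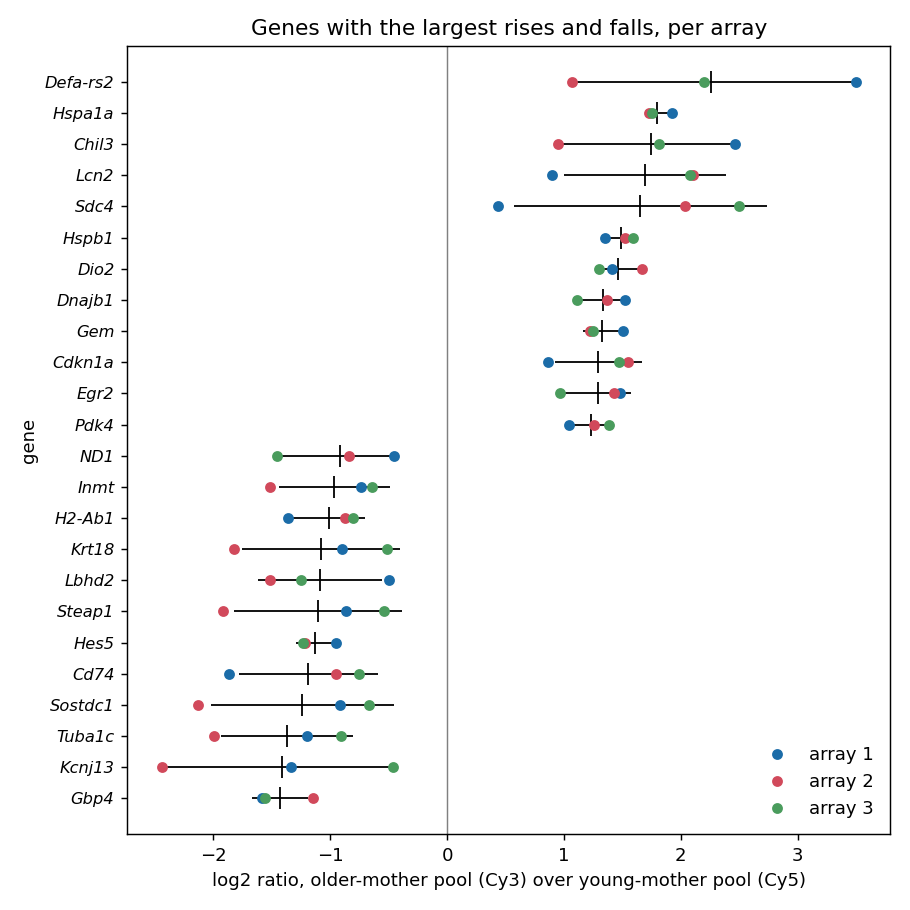
Log2 ratios of older over young mothers (horizontal axis) for the 12 largest rises and 12 largest falls; each point is 1 array, the tick is the mean and the line is 1 SD on either side (n = 3 arrays). Hspa1a lies between 1.73 and 1.92 on the 3 arrays, and Kcnj13 between -2.44 and -0.46.

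Of the gene and marker lists fixed in advance, 52 had enough measured genes to test, and 9 were shifted by limma's camera with a preset correlation of 0.01 (Benjamini-Hochberg adjusted p under 0.05): 6 up and 3 down. With a correlation estimated from the data 0 lists were called, the smallest adjusted p was 0.759 and the smallest unadjusted p 0.0371. For the 9 lists the estimated correlations ran from -0.04 (histones) to 0.73 (choroid plexus), with 0.70 for glucocorticoid-induced genes. The preset one treats the genes of a list as nearly independent, so its p does not measure how a list as a whole varied between arrays. Correlation between genes does not account for all of the lost calls. The histone list, at -0.04, went from an unadjusted camera p of 0.000633 to 0.0676. The simulated list, without correlation between genes, was missed too with an estimated one (camera adjusted p = 0.222). With fry, 3 lists were called, 2 of them among the 9 (heat shock proteins and histones).

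Glucocorticoid-induced genes rose in 16 of 20 measured members, and 4 did not pass; adjusted over the list alone, 17 rose and 0 fell. Their median log2 ratio was 0.69, with array medians of 0.61, 0.78 and 0.70 (camera adjusted p = 4.4e-12, from 5.2e-15 over the alternatives up to adjusted p = 0.759 with an estimated correlation). Examples are Sgk1, a serum- and glucocorticoid-regulated kinase, at 0.98 ± 0.11, Nfkbia, the NF-kappaB inhibitor, at 0.83 ± 0.03, and Zbtb16, a zinc finger transcription factor, at 0.64 ± 0.04 (each SD, n = 3); under median centring the sign of Zbtb16 turned (-0.035), and it stayed above the median of all genes there. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose by 0.49 ± 0.19 (SD, n = 3, limma adjusted p = 0.0225), and its value was -0.12 under median centring, above the median of all genes there. Nr3c1, the glucocorticoid receptor itself, had a log2 ratio of 0.03 ± 0.08 (SD, n = 3) with a limma adjusted p of 0.680. It was -0.59 under median centring (-0.18 relative to the median of all genes there) and -0.02 without replicate 1. Its other probe had the opposite sign.

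Immediate early genes, which neurons switch on after activity, rose in 15 of 22 members, and 7 did not pass; adjusted over the list alone, 17 rose and 0 fell. Their median was 0.52, with array medians of 0.54, 0.55 and 0.47 (camera adjusted p = 1.9e-10, from 2.0e-13 over the alternatives up to adjusted p = 0.759 with an estimated correlation). Fos rose by 1.21 ± 0.26, Npas4 by 0.98 ± 0.16, Nr4a2 by 0.98 ± 0.20 and Fosb by 0.93 ± 0.16 (each SD, n = 3); all 4 are transcription factors. Bdnf, a neurotrophin, had a log2 ratio of 0.30 ± 0.22 (SD, n = 3, limma adjusted p = 0.0672). It became -0.24 under median centring, 0.17 above the median of all genes there.

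Heat shock proteins rose in 11 of 15 members, and 4 did not pass; adjusted over the list alone, 13 rose and 0 fell. Their median was 0.65, with array medians of 0.63, 0.47 and 0.82 (camera adjusted p = 1.9e-10, from 2.0e-13 over the alternatives up to adjusted p = 0.759 with an estimated correlation). Beside Hspa1a, Hspb1 and Dnajb1, the co-chaperone Dnaja1 rose by 0.83 ± 0.02 (SD, n = 3). Unfolded protein response genes rose in 12 of 17 members, 1 fell (Trib3, a pseudokinase, at -0.41) and 4 did not pass; adjusted over the list alone, 12 rose and 2 fell. Their median was 0.58, with array medians of 0.33, 0.57 and 0.78, and under median centring it turned to -0.09, which lies 0.32 above the median of all genes there. The camera adjusted p was 2.1e-05, with 0.759 for an estimated correlation and 0.138 under median centring; over all alternatives it ran from 6.1e-07 to 0.759. Creld2, a protein of the endoplasmic reticulum, rose by 0.93 ± 0.18, Xbp1, a transcription factor of the response, by 0.79 ± 0.06, the disulfide isomerase Pdia6 by 0.79 ± 0.21 and Herpud1 by 0.70 ± 0.16 (each SD, n = 3). Under median centring the medians of the glucocorticoid, activity and heat shock lists were 0.064, 0.27 and 0.080. Relative to the median of all genes there they were 0.47, 0.68 and 0.49, and the camera calls of these 3 lists held. Over the alternatives with the preset correlation, the highest camera adjusted p of these lists were 0.00113, 1.4e-05 and 0.0272.

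**Figure D2:**
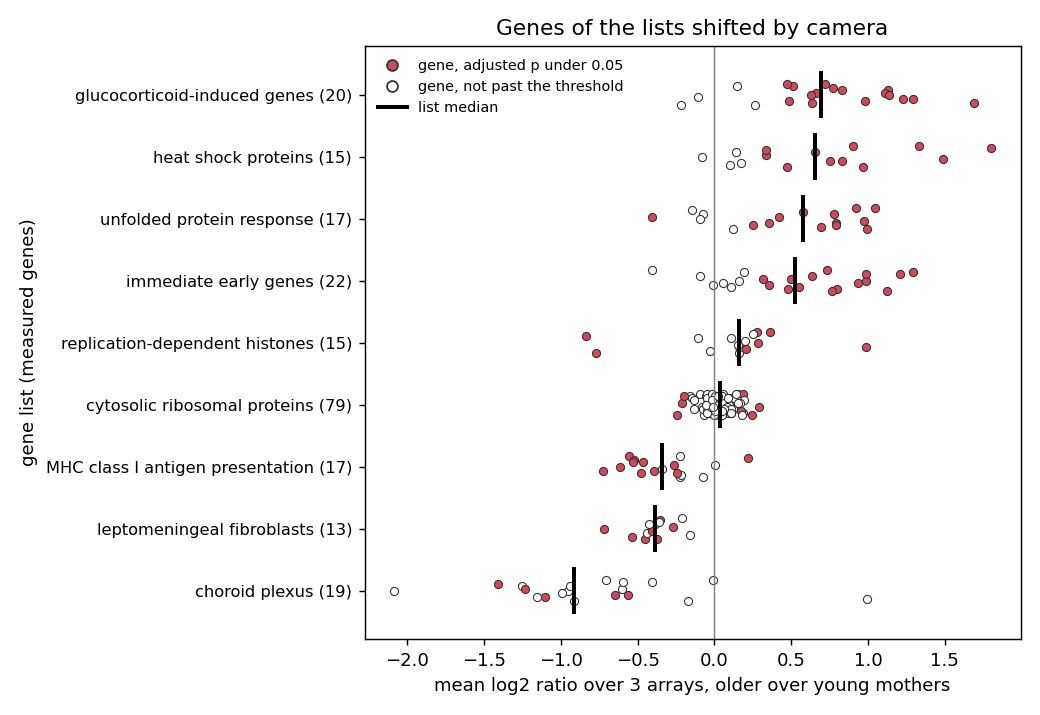
Mean log2 ratio of each measured gene (points; filled where the limma adjusted p is under 0.05) and list median (bars) for the 9 shifted lists, with the number of measured genes in parentheses. List medians run from -0.92 for choroid plexus markers to 0.69 for glucocorticoid-induced genes; under median centring the medians of the unfolded protein response (-0.09), histone (-0.22) and ribosomal (-0.78) lists turn negative.

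Choroid plexus markers fell in 5 of 19 members, and 14 did not pass; adjusted over the list alone, 0 rose and 15 fell. Their median was -0.92, a 1.89-fold difference, and it varied between arrays, at -0.62, -1.75 and -0.33; without replicate 2 it was -0.46. Under median centring the list median was -1.36, which lies 0.96 below the median of all genes there. The camera adjusted p was 0.00106, with 0.759 for an estimated correlation and 0.622 under median centring, where the spread (SD) of the log2 ratios over genes was 0.42 against 0.20; over all alternatives it ran from 5.3e-08 to 0.759. Ttr, the thyroxine carrier that the choroid plexus secretes, had log2 ratios of -1.67, -3.95 and -0.63 on the 3 arrays, with a mean of -2.08 ± 1.70 (SD, n = 3) that did not pass (limma adjusted p = 0.0645). Among the members that fell were Slc4a5, a bicarbonate transporter, at -0.65 ± 0.39 and Cab39l at -0.57 ± 0.25 (each SD, n = 3). Kcne2, a potassium channel subunit, was the only member of the list with a mean above 0, at 1.00 ± 1.94 (SD, n = 3), and did not pass. It was -0.53, 0.34 and 3.18 on the arrays, so its mean rests on array 3. Of the largest falls outside the list, Krt18, Inmt and Tuba1c had the same order of arrays, array 2 lowest and array 3 nearest to 0. Gbp4, Cd74, Hes5, Lbhd2, H2-Ab1 and ND1 did not.

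Leptomeningeal fibroblast markers fell in 7 of 13 members, and 6 did not pass; adjusted over the list alone, 0 rose and 11 fell. Their median was -0.38, with array medians of -0.39, -0.56 and -0.18, the same order of arrays as for the choroid plexus. Under median centring the list median was -0.81, which lies 0.41 below the median of all genes there. The camera adjusted p was 0.000297, with 0.759 for an estimated correlation and 0.0724 under median centring; over all alternatives it ran from 1.6e-07 to 0.759. Igf2, an imprinted growth factor of the meninges and choroid plexus, fell by 0.72 on the log2 scale (SD 0.36, n = 3). Aldh1a2, which makes retinoic acid, was at -0.46 ± 0.14, the proteoglycan Ogn at -0.40 ± 0.10 and the proteoglycan Fmod at -0.36 ± 0.07 (each SD, n = 3), and all 3 fell. Igf2 and Aldh1a2 had the order of arrays of the list median. Ogn and Fmod did not, and were lowest on array 3 and nearest to 0 on array 1.

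Genes of antigen presentation on MHC class I fell in 10 of 17 members, 1 rose (H2-Q4, a class I chain, at 0.22, but -0.59 under median centring) and 6 did not pass; adjusted over the list alone, 1 rose and 12 fell. Their median was -0.34, with array medians of -0.51, -0.25 and -0.25, an order unlike that of the choroid plexus. The median was -0.75 under median centring, 0.34 below the median of all genes there. The camera adjusted p was 0.000394, with 0.759 for an estimated correlation and 0.124 under median centring; over all alternatives it ran from 1.5e-06 to 0.759. Psmb9 and Psmb8, subunits of the immunoproteasome, fell by 0.73 and 0.53 on the log2 scale (SD 0.19 and 0.17, n = 3), and the class I chains H2-M3 and H2-T23 were at -0.56 ± 0.17 and -0.53 ± 0.16 (each SD, n = 3). On MHC class II, 5 of 8 members fell, 1 rose (Ciita, the class II transactivator, at 0.31) and 2 did not pass; the same counts held adjusted over the list alone. H2-DMb1, a peptide-loading chain, was at -0.71 ± 0.28 (SD, n = 3), and the class II list was not called (median -0.46, camera adjusted p = 0.0923). Without each replicate in turn it was called (0.0464, 0.0256 and 0.0144), and over all alternatives its adjusted p ran from 0.0144 to 0.761. Of 21 interferon-stimulated genes 5 fell, 0 rose and 16 did not pass (6 fell adjusted over the list alone), and that list was not called either (median -0.15, camera adjusted p = 0.0520; 0.00604 without replicate 2 and 0.0107 without replicate 3, with a range over all alternatives from 0.00604 to 0.759). Gbp3, an interferon-induced GTPase, was at -0.81 ± 0.20 (SD, n = 3). Irf7, a transcription factor of the interferon response, was not above background in the older-mother pools, all in Cy3. It was 1.25-fold lower, but its value turned to 0.24 under median centring.

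**Figure D3:**
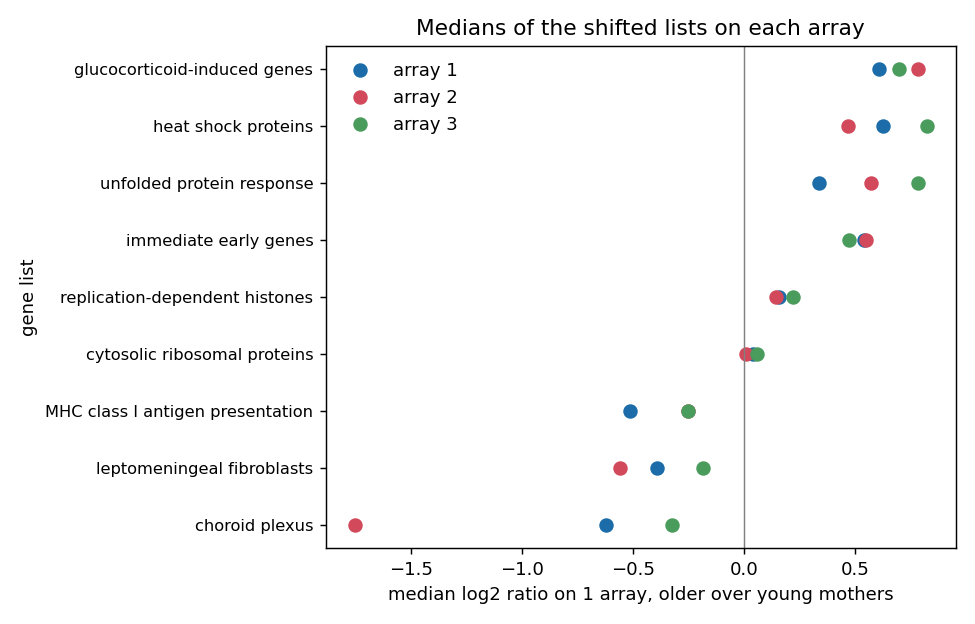
Median log2 ratio of the measured genes of each shifted list on array 1, 2 and 3 (points). The choroid plexus medians run from -1.75 to -0.33 and the immediate early gene medians from 0.47 to 0.55; under median centring the medians of the unfolded protein response, histone and ribosomal lists turn negative.

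Replication-dependent histones rose in 5 of 15 members, 2 fell (H4f16 at -0.77 and H4c4 at -0.84) and 8 did not pass; adjusted over the list alone, 9 rose and 2 fell. Their median was 0.16, and under median centring it turned to -0.22, which lies 0.19 above the median of all genes there. The camera adjusted p was 0.00411, with 0.759 for an estimated correlation and 0.666 under median centring; over all alternatives it ran from 0.00243 to 0.759. Hist2h2bb was at 0.99 ± 0.14 (SD, n = 3). Hist3h2a (0.36 ± 0.08), H3c13 (0.28 ± 0.08) and H2ac4 (0.28 ± 0.10, each SD, n = 3) rose too, but turned to -0.26, -0.085 and -0.22 under median centring. Relative to the median of all genes there these 3 were at 0.15, 0.32 and 0.19. Cytosolic ribosomal proteins had a median of 0.03 that turned to -0.78 under median centring, 0.38 below the median of all genes there, with opposite camera calls in the main and the centred data (adjusted p = 0.0196 and 1.5e-07). Of 79 measured ribosomal genes 4 rose, 3 fell and 72 did not pass, and adjusted over the list alone 0 did; the call ended without replicate 1 (adjusted p = 0.0794), without replicate 3 (0.0653), with no filter (0.0993), with base composition removed (0.205), with fry (0.288) and with an estimated correlation (0.759). Rplp0 (0.29 ± 0.05) and Rps18 (0.25 ± 0.03) were higher, and turned to -0.51 and -0.48 under median centring, and Rpl38 (-0.25 ± 0.08) and Rpl23 (-0.21 ± 0.06, each SD, n = 3) were lower; both other probes of Rpl23 and the other probe of Rps18 had the opposite sign.

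Marker lists of the main hippocampal cell types were not called, and for those that follow the counts were the same adjusted over the list alone. Dentate granule neuron markers had a median of 0.14 (camera adjusted p = 0.0520; 0.0144 without replicate 2 and 0.0261 without replicate 3, with a range over all alternatives from 0.0144 to 0.971). Of 11 measured, 1 rose: Dock10, a Rac and Cdc42 exchange factor, at 0.41 ± 0.06 (SD, n = 3), which turned to -0.18 under median centring. Of the markers of CA1, CA2 and CA3 pyramidal neurons 0 of 9, 0 of 7 and 0 of 7 passed in limma (4, 1 and 1 at an unadjusted p under 0.05), with medians of -0.02, -0.15 and -0.12 (camera adjusted p = 0.566, 0.378 and 0.495); fry called the CA2 list down (adjusted p = 0.0340, the lowest over its alternatives, which reached 0.759). Of 15 astrocyte markers 2 rose and 13 did not pass: the connexin Gjb6 at 0.75 ± 0.25 and the intermediate filament gene Gfap at 0.48 ± 0.12 (each SD, n = 3), where Gfap turned to -0.16 under median centring and 1 of its 2 other probes had the opposite sign. The astrocyte median was -0.02 while its mean was 0.05 and its test pointed up (camera adjusted p = 0.495). Among 16 microglial markers the fractalkine receptor Cx3cr1 fell (-0.46 ± 0.08) and the complement gene C1qa rose (0.31 ± 0.05, each SD, n = 3; -0.25 under median centring), and the list median was -0.01 with a test that pointed up (camera adjusted p = 0.554). Of 14 endothelial markers 1 rose and 6 fell, with a median of -0.15 (camera adjusted p = 0.422). The tight junction gene Cldn5 was at -0.63 ± 0.22 and the VEGF receptor gene Flt1 at 0.38 ± 0.07 (each SD, n = 3; -0.24 for Flt1 under median centring). Of the 2 other probes of Flt1, 1 had the opposite sign. Relative to the median of all genes under median centring, Dock10, Gfap, C1qa and Flt1 stayed above 0, at 0.22, 0.25, 0.15 and 0.16.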

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

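Tests chosen only after the result was seen are those of a dye effect shared by all probes of a gene and of handling or time of death, the regression on base composition, the list medians relative to the median of all genes under median centring, and the requirement that the exact interval of a share of second probes exclude 60%.

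Control spots of the ERCC class, which no comparison here uses, were well above background in 4.17% of spots in Cy3 and 18.1% in Cy5, against 0.218% and 0.436% of the negative controls (120 ERCC spots per array). Control spots of the ETG class were well above background in 9.23% of spots in Cy3 and 10.8% in Cy5 (130 spots per array).

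The log ratios were shared by the 3 arrays, and a dye difference would be shared in the same way. The tables argue against base composition of the probes as the whole source, since the mean log2 ratio had an R squared of 0.0529 on it. After a regression on it 1879 probes were higher and 2567 lower, of which 1623 and 2245 were among the main calls. A dye effect tied to single probe sequences is argued against for genes with at least a 1.5-fold change that had a second, non-overlapping probe, 42 of 195. Of these second probes 38 (90.5%, exact 95% interval 77.4 to 97.3) lay on the same side of 0, with a median of 0.36 against 0.75 for the called probes, and 22 were called on that side. For the other genes with such a change it was not tested. For the called genes under 1.5-fold it stays open, as 630 of 915 second probes lay on the same side (68.9%, interval 65.7 to 71.8, medians 0.079 against 0.27), against 56.8% for genes that were not called. A dye effect shared by all probes of a gene cannot be told apart from the group difference, as 0 arrays had the older-mother pool in Cy5; a difference between the offspring of older and young mothers stays open too, untested against it. Only 4 distinct orientations of the arrays exist, too few for a share under 0.05: the real one gave 5135 probes past the threshold, 1 of 4 orientations gave as many, and the highest other gave 0.

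Stress and activity genes were higher on all arrays by list median, in 54 called genes of 4 lists. By a measure chosen after the result was seen, the tables argue against the loess or background setting as the whole source in the glucocorticoid, activity and heat shock lists. Under median centring, which moved the median of all genes to -0.40, these lists lay 0.47, 0.68 and 0.49 above that median (main medians 0.69, 0.52 and 0.65), at least 0.36 on each array. Their camera calls held, and without background correction the 4 list medians were 0.948 to 0.998 times the main ones. The setting stays open for the unfolded protein response list, which lay 0.32 above the median of all genes (SD 0.093, at least 0.28 on each array, main median 0.58) but lost its camera call. Whether the smaller distance or the wider spread (SD) over genes, 0.42 against 0.20, ended that call was not tested. The setting's part in the sizes cannot be told apart, as that shift of all genes dominates the ratio to the main median. That ratio was the test fixed before the data were examined. It was 0.092, 0.52, 0.12 and -0.154 for the glucocorticoid, activity, heat shock and unfolded protein response lists. All but the activity list came out on the side of the setting in it. A dye effect tied to single probe sequences stays open, as 8 of 10 second probes (80%, exact 95% interval 44.4 to 97.5) lay above 0. Handling or time of death that differed between the groups cannot be told apart from maternal age, which stays open untested, as 0 label fields give an order or a time of day.

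Choroid plexus markers were lower, with list medians of -0.62, -1.75 and -0.33 on the arrays. A dye effect tied to single probe sequences is argued against, as 100% of the 10 second probes (exact lower bound 69.2%) lay below 0. Less choroid plexus in the dissected tissue of the older-mother pools cannot be told apart from lower expression per choroid plexus cell, a difference between the groups that stays open untested. Of the 5 brightest markers (Ttr, Cab39l, Clic6, Kl and Kcnj13) 5 had an upper 95% bound below 0, at mean log2 intensities from 15.4 for Ttr to 9.96 for Kcnj13, and both explanations give that. Of the list's members Ttr also stands in the thyroid hormone list.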

How the results depend on the processing

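The base composition regression and the list tests without choroid plexus and leptomeningeal genes were chosen only after the data were seen. They gave 1879 higher and 2567 lower probes with 13 lists, and 7 lists. Leaving these genes out took the choroid plexus and leptomeningeal lists themselves out of the test. The other 50 lists kept their call or lack of a call. Probe counts of 2189 higher and 2946 lower became 1169 and 1449 with Agilent's processed signals, 5970 and 17033 with median centring, 5747 and 7543 with array weights, 152 and 87 with at least a 1.5-fold change and 3862 and 5210 at an adjusted p under 0.10. The last 2 follow from the threshold, and for the others the cause was not tested. Of the calls with processed signals, 858 higher and 970 lower probes were among the main calls. For median centring these numbers were 653 and 2261, and for array weights 2188 and 2939. Leaving out 1 replicate, which leaves 1 residual degree of freedom, gave 29 to 1459 higher and 0 to 1906 lower probes (29 and 0 without replicate 3, with 8422 at an unadjusted p under 0.05) and 10 to 15 shifted lists, against 9. An estimated correlation gave 0 lists and fry 3. The former also missed a simulated shift, in lists without correlation between genes. Some lists without a main call were called, in their main direction, under alternatives on all 3 arrays. These were 5 with base composition removed, 4 under median centring and 3 with the deposited table. There were 2 with no filter, 2 with the mean over probes, 1 without background correction and 1 with fry. Both probe counts stayed within 1.5 times under the offset of 16, no background correction, scaling between arrays, the deposited table, both filters, the variance trend and separate channels. Called probes with the opposite sign numbered 1351 under median centring and 0 under each of the other settings.

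Of 143 named genes 124 were past the threshold, and 54 of these lost it with Agilent's processed signals and 26, 60 and 110 without replicates 1, 2 and 3. Under median centring 39 changed sign: Gfap -0.16, Bdnf -0.24, Nr3c1 -0.59, Fkbp5 -0.12, Rgs9 -0.14, Rgs16 -0.027, Slitrk6 0.095, Ccn2 -0.34, Ucn3 0.18, Dock10 -0.18, Stxbp6 -0.45, Wfs1 -0.40, Sox11 -0.14, Neurod1 -0.057, Ermn -0.30, C1qa -0.25, Flt1 -0.24, Zbtb16 -0.035, Irf7 0.24, Klf9 -0.047, Grin2c -0.24, Gabra2 -0.31, Gabbr2 -0.19, Htr4 -0.057, Scn1a -0.33, Scg2 -0.41, Gfra2 -0.31, Ntrk2 -0.50, Irs2 -0.15, Rplp0 -0.51, Rps18 -0.48, Psmd7 -0.35, Psmd11 -0.31, Kdm6b -0.060, Idi1 -0.21, Fzd2 -0.10, Hist3h2a -0.26, H3c13 -0.085 and H2ac4 -0.22. The ribosomal and proteasome list medians became -0.78 and -0.66. The median of all genes moved to -0.40 there; relative to it 14 named genes had the opposite sign, and relative to 200 genes of like intensity, which nearly repeats the loess step by construction, the 39 kept theirs. Nr3c1 was -0.0064 with array weights and -0.017 to 0.059 without 1 replicate. Signal over background limits the dim probes, of which 1448 were not above background in Cy3 on any array.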

Other observations

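The test of chromosome windows was chosen before the result was seen, and the members named beside the rule were chosen after their values were seen.

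Clock genes went both ways. Of 21 measured, 5 rose, 2 fell and 14 did not pass (5 and 3 adjusted over the list alone), with a median of 0.08 and a camera adjusted p of 0.422. Nr1d1, a repressor of the clock, fell by 0.69 on the log2 scale (SD 0.03, n = 3), and Nfil3, a transcription factor in antiphase to it, was at 0.66 ± 0.11, Per1 at 0.47 ± 0.13 (-0.14 under median centring) and Per2 at 0.44 ± 0.14 (each SD, n = 3). Of 19 thyroid hormone genes 3 rose, 3 fell and 13 did not pass (6 and 4 adjusted over the list alone). Besides Dio2, Klf9, a target of thyroid hormone and glucocorticoids, rose by 0.63 ± 0.13 (SD, n = 3; -0.047 under median centring). The thyroid list median was -0.06 while its test pointed up (camera adjusted p = 0.562). Of 10 blood leukocyte markers 4 rose, 1 fell and 5 did not pass, with the same counts adjusted over the list alone (median 0.07, camera adjusted p = 0.111, and 0.0342 without replicate 2, with a range over all alternatives from 0.00694 to 0.759). The lowest camera adjusted p, 0.00694, came from an alternative on all 3 arrays. S100a9 and S100a8, which form calprotectin of neutrophils, were at 1.19 ± 0.50 and 0.48 ± 0.24, Plac8, whose other probe had the opposite sign, at 0.28 ± 0.02 and the cathelicidin Camp at 0.33 ± 0.12 (each SD, n = 3). Irs2, an adaptor of the insulin receptor, rose by 0.51 ± 0.09 (SD, n = 3, with -0.15 under median centring), in a list of 23 with 1 rise and 2 falls (1 and 1 adjusted over the list alone, camera adjusted p = 0.774). Relative to the median of all genes under median centring, Klf9 and Irs2 stayed above 0, at 0.36 and 0.26.

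In the counts that follow, the second pair of numbers, where given, is adjusted over the list alone; elsewhere it was the same. Among synaptic groups, 2 of 28 synaptic vesicle genes rose and 4 fell (camera adjusted p = 0.464; called down under median centring at 0.0274, with a range over all alternatives from 0.0274 to 0.909), with the active zone gene Pclo, where 1 of 3 other probes had the opposite sign, at -0.41 ± 0.04 and Sv2a at -0.37 ± 0.12 (each SD, n = 3). Of 22 glutamate receptor genes 2 rose and 3 fell (2 and 4, camera adjusted p = 0.951): the NMDA receptor subunit Grin1 was at -0.28 ± 0.04 and Grin2c at 0.35 ± 0.03 (each SD, n = 3; -0.24 for Grin2c under median centring). Of 26 sodium and calcium channel genes 3 rose and 2 fell (4 and 4, camera adjusted p = 0.566), with the sodium channel Scn8a at -0.46 ± 0.10 (SD, n = 3), where 1 of its 2 other probes had the opposite sign. Of 28 potassium channel genes 3 rose and 4 fell (4 and 4, camera adjusted p = 0.495), with Kcna4 at -0.41 ± 0.06 (SD, n = 3). Of 27 imprinted genes 3 rose and 5 fell (4 and 7, camera adjusted p = 0.422), with Magel2 at -0.50 ± 0.07 and Dlk1 at -0.35 ± 0.04 (each SD, n = 3). Of 21 cholesterol synthesis genes 3 rose and 0 fell (camera adjusted p = 0.0506; 0.00352 without replicate 1 and 0.0358 without replicate 2, with a range over all alternatives from 0.00352 to 0.759), with the demethylase Cyp51 at 0.44 ± 0.14 (SD, n = 3). Of 29 histone and DNA modifier genes 3 rose and 2 fell (camera adjusted p = 0.422), with the histone demethylase Kdm6b at 0.44 ± 0.08 (SD, n = 3, with -0.060 under median centring). Relative to the median of all genes under median centring, Grin2c and Kdm6b stayed above 0, at 0.16 and 0.34. Of 75 respiratory chain genes 2 rose and 6 fell (0 and 1, camera adjusted p = 0.481; called down under median centring at 1.5e-07, with a range over all alternatives from 1.5e-07 to 0.759). Of 11 pericyte and smooth muscle markers 0 rose and 5 fell (2 and 6, camera adjusted p = 0.119; 0.0172 without replicate 3, with a range over all alternatives from 0.0172 to 0.862), with Vtn at -0.39 ± 0.04 and Acta2 at -0.40 ± 0.08 (each SD, n = 3). The serotonin receptor gene Htr2c (-0.62 ± 0.25), Sfrp5 (-0.80 ± 0.39) and Crhr2 (-0.43 ± 0.20, each SD, n = 3) fell with array 2 lowest, as the choroid plexus markers did. The lists not described had camera adjusted p of 0.0901 or more, and 4 of them were called under an alternative. Collagens and extracellular matrix were called down without replicate 3 (0.0129), without background correction (0.0284), with the deposited table (0.0445) and with base composition removed (0.0430), with a range over all alternatives from 0.0129 to 0.759. Oligodendrocytes and myelin were called up without replicate 2 (0.0238, range 0.0238 to 0.941). Under median centring the proteasome list (0.00152, range 0.00152 to 0.759) and the antioxidant list (0.0274, range 0.0274 to 0.994) were called down.

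A strain or passenger region differing between the groups was tested as a source of called changes grouped on chromosomes: over 546 windows of 5 Mb, counting called genes with at least a 1.5-fold change (193 with a position), the smallest adjusted p was 0.454, so no window passed. The window with the smallest p held 5 such genes of 68, all of histone names, with 0.733 expected.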
